A study of Vitis vinifera with 70 samples.

How the data were processed

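The samples were 70 labelled RNA samples from Cabernet Sauvignon berry pericarp, 1 per spot and time point (14 spots, 5 time points), each hybridised to its own one-colour (Cy3) custom Agilent array. The deposited scanner files hold spot intensity on a linear scale, made with Agilent Feature Extraction 10.5.1.1 and the protocol GE1_105_Dec08, per the file headers: the processed signal is the background-corrected intensity of a spot, and median foreground and background intensity stand beside it. Other deposited columns hold flags for control spots, spots well above background, saturated spots and outlier spots, with values of 0 or 1 in the columns used, per the file headers. The authors' deposited value table holds the processed signal intensity of the same 70 arrays, each multiplied by a factor of its own that brings the 75th percentile to 1370. This was found by setting each column against the scanner values of its array (SD of the log2 ratio 0.0019 to 0.0028), so its scale is a linear one and no centring or direction is left unknown; the medians of its columns ran from 96.7 to 218.0. How RNA quality was checked is not given in the sources used here.

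Spot numbers pair the samples by design: per the labels, a number marks the same square of vines and the same marked clusters at each sampling. The replicates of a time point are therefore 14 separate plots of a single vineyard in a single season. Deviations of arrays of one spot from the mean of their time point and array set had a mean correlation of -0.034 over 140 pairs, against 0.205 ± 0.183 (SD, 191 pairs) for arrays of different spots and time points on one slide and -0.047 for different slides. All arrays of 9 spots lay on slides 1 to 6 (array set 1, 45 arrays) and all arrays of 5 spots on slides 7 to 10 (array set 2, 25 arrays), and most slides held several time points. Slide and scan coincided. The 75th percentile of the processed signal ran from 504.8 to 2270.4, with a mean of 1620 ± 254 in set 1 and 920 ± 329 in set 2 (SD).

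For the analysis, log2 of the processed signal minus each array's 75th percentile was used. Control spots (1319 per array) were left out, spots with an outlier flag were set to missing (15644 spots, 0.65%), and no spot was saturated. The 34369 remaining probes have 1 identifier each, 29798 of the VIT form, 4392 of the XLOC form and 179 others, so no rule for several probes of a gene was needed. A probe was tested if it was well above background on at least 7 of the 14 arrays of at least 1 time point, which left 27207. Consecutive time points were compared in a single limma fit over all 70 arrays with time point as the factor (R 4.3.3, limma 3.58.1, lmFit and eBayes). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 change of at least 1, and "rose" and "fell" are used for such genes. Where a probe was not well above background on any array of a time point, its fold is a bound, computed against the higher of its own signal and the lowest signal of a probe well above background on the array. Changes are relative to the 75th percentile of the arrays and not to an absolute amount of RNA. For spots, a moderated F test compared the fits with and without spot, within array set and after time point by array set.

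Distance and transcriptome day were computed with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1; figures with matplotlib 3.10.9). The day is the position of the nearest point on the broken line through the 5 time point means of the other 13 spots, with the end segments extended, read on the sampling calendar. Paired values were compared by exact sign flips (16384 of them, two-sided), and correlations over 14 spots and list scores by permutation tests with 100000 resamples (two-sided for correlations; for list scores, spot labels permuted within array set and time point). Correlations within the 9 spots of set 1 used exact permutations. Benjamini-Hochberg adjustment covered each family of tests. Missing spots were filled with the mean of their time point for list tests. For list scores, and for the spot test with slide as a random block, they were filled with the mean of their time point and array set. Distances and transcriptome days left them out.

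Gene names need a caution. The files pair no names or descriptions with identifiers, and 0 of the 34369 identifiers matched the table of RefSeq gene names that was at hand. Lists of genes by identifier, with the names used in grapevine research, were fixed before the data were examined and were written from general knowledge. A check on chromosome was possible for 18 of 38 such names, which the RefSeq table holds: 17 lay on the chromosome that the identifier gives, and 1 identifier (ANR) is on no chromosome. The check says nothing about the order of genes within a chromosome, and every name is to be read as listed, not as an annotation of the array. The stilbene synthase list (identifier ranges, 45 tested) and the phenylalanine ammonia-lyase list (13) were written after the files were opened and before any expression value was seen. Their members, like the flavonoid 3',5'-hydroxylases, are mostly tandem copies of near-identical sequence, so probes may share targets, and counts of members are uncertain. Of 32 lists defined, 21 were defined by words in descriptions and could not be filled, among them the markers of seed, cuticle and vascular tissue, so carry-over from other tissues was not analysed here. Of the other 11, those with at least 5 tested members (6 lists) were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, which gave 16 and 0 calls of 24 (18 and 8 at an unadjusted p under 0.05).

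The rule for named genes, also fixed beforehand, took up to 3 members of each list with the largest change past both thresholds, allowed any single gene of the lists to be named, and took the genes with the largest changes of one sign in at least 13 of 14 spots; of these last, which carry no name here, 2 up and 2 down are given per interval. For the spots, the 3 genes with the lowest p are given. Alternatives covered background correction (normexp with an offset of 50 on the median intensity, since the mean was not among the columns, followed by quantile normalization), quantile normalization alone, the deposited value table, the filter (none, or all 14 arrays of a time point), the spot as a replicate block, slide as a random or fixed block (random: correlation 0.195 in the time fit and 0.199 in the spot fit, from 3000 genes), each array set alone, no minimum change, each spot or time point left out, other gene subsets, and the array of spot 7 at time point 2 left out.

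The procedures were tested on simulated data. For time points 4 to 5 with 27207 genes, 88 of 100 genes changed by a log2 of 1.5 and 100 of 100 changed by 3 were called, with 2 unchanged genes called. For the spot test, 77 of 100 genes with a spot SD equal to the residual SD and 100 of 100 at an SD 2 times as large were called, with 7 unchanged genes called. The camera step called the changed list with both correlations and 0 unchanged lists, and the transcriptome day was recovered with a mean absolute error of 0.63 days over 70 arrays (r = 0.961 with the simulated shift). In all these simulations genes varied independently of each other, without slide effects, and simulated days stayed within the sampling calendar. They therefore do not show how the procedures behave with correlated list members or with arrays that share a slide.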

Results

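Transcript levels were measured in berry pericarp (skin and pulp, seeds removed) of the red wine grape Cabernet Sauvignon from 14 spots of a single vineyard, at 5 samplings labelled time points 2, 4, 5, 6 and 8. The first 4 samplings were 10, 30, 39 and 51 days after the berries were pea-sized and the last was harvest. The sampling dates, counted from the first, put them on days 0, 21, 30, 42 and 78, and this calendar, which exceeds the stated days after pea size by 1 day from time point 4 to 6, was used below. A spot was a small square of adjacent vines, and berries came from the same marked clusters of a spot at every sampling, so each time point had 14 samples and the whole set 70 one-colour microarrays. Between 56.4 and 88.3% of probes were well above background on an array (median 71.3%), and the number of arrays limited the precision of each value. The arrays lay on 10 slides in 2 sets: set 1 held all samples of 9 spots and set 2 all samples of the other 5 spots. After filtering, 27207 genes were tested. Genes are given by the identifiers of the array, and a gene name beside an identifier is the one listed for it before the data were examined, since the files pair no names with identifiers. The first principal component carried 47.2% of the variance over 21726 genes and ordered the time points without overlap, from -147.8 to -120.3 at time point 2 up to 158.0 to 190.4 at time point 8.

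**Figure D1:**
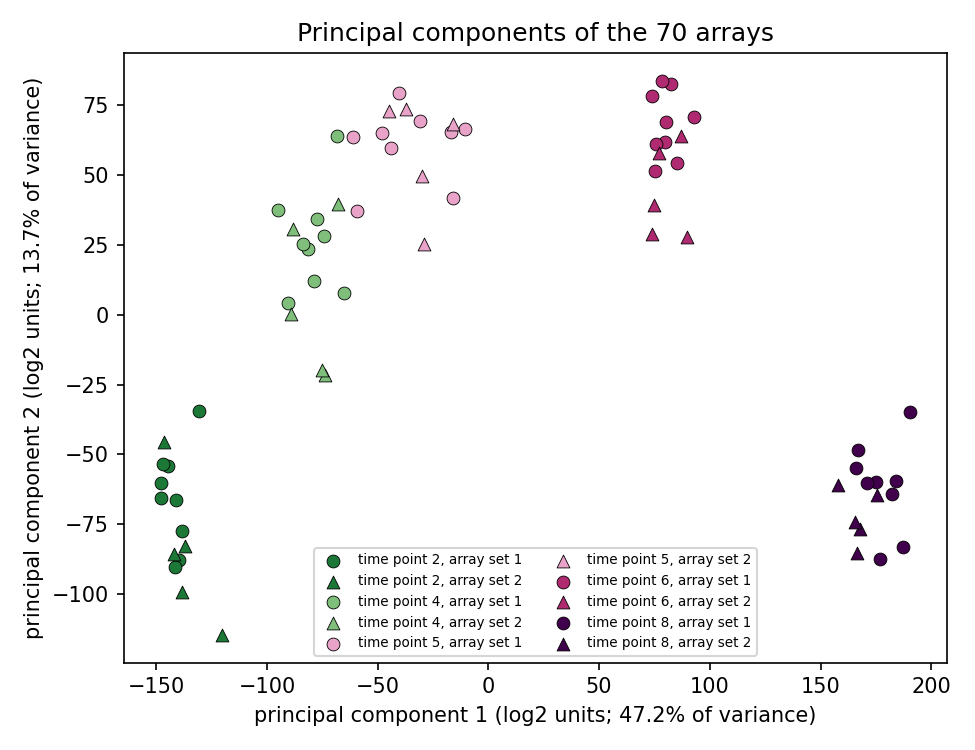
Scores of the 70 arrays on principal component 1 (x axis, 47.2% of variance) and principal component 2 (y axis, 13.7%), both in log2 units; each point is the array of 1 spot at 1 time point, coloured by time point, with circles for array set 1 and triangles for array set 2. The time points do not overlap on the x axis, and time point 5 (-61.4 to -10.5) is separated from time point 6 (74.0 to 92.8) by a wider gap than from time point 4 (-95.1 to -65.3).

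The first interval, from time point 2 to time point 4, showed falling transcripts of early phenylpropanoid and flavonoid genes and rising transcripts of 4 of 5 listed NAC transcription factors. The NAC list was a choice made beforehand and does not stand for the whole family. Of 13 phenylalanine ammonia-lyase genes, which encode the entry enzyme of the phenylpropanoid pathway, 12 fell and 0 rose, with a median log2 change of -3.28; VIT_08s0040g01710 fell by 3.95 ± 0.29 (SE) log2 units and was lower in 14 of 14 spots. Of 10 flavonoid core genes, 8 fell and 1 rose, with a median of -2.22. Flavanone 3-hydroxylase F3H1 (VIT_04s0023g03370) fell by 3.49 ± 0.24 log2 units (11.2-fold, limma adjusted p = 8.2e-20), chalcone synthase CHS2 (VIT_14s0068g00920) fell by 2.83 ± 0.20 and leucoanthocyanidin dioxygenase LDOX (VIT_02s0025g04720) fell by 2.81 ± 0.16. The exception that rose was flavonol synthase FLS (VIT_18s0001g03470), by 1.37 ± 0.26. Anthocyanidin reductase ANR (VIT_00s0361g00040), which makes precursors of condensed tannins, fell by 4.01 ± 0.29 log2 units (16.1-fold, adjusted p = 1.6e-19), whereas the other 7 members of the proanthocyanidin list did not pass the test.

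Among 21 anthocyanin branch genes, 10 fell and 3 rose between time points 2 and 4, with a median of -0.97. All 10 that fell were identifiers listed as flavonoid 3',5'-hydroxylases, which set the hydroxylation of anthocyanins and flavan-3-ols, with changes of -5.21 to -1.98 log2 units. The 3 that rose were the transporter anthoMATE1 (VIT_16s0050g00930), by 1.05 ± 0.12, and the MYB regulators MYBA1 (VIT_02s0033g00410) and MYBA2 (VIT_02s0033g00390), by 1.04 ± 0.44 and 1.1 ± 0.39 from levels near background, since neither was above background on more than 5 of the 14 arrays of a time point. Of 5 NAC genes, 4 rose, including NAC26 (VIT_01s0026g02710) by 3.28 ± 0.23 (9.69-fold) and NAC60 (VIT_08s0007g07670) by 2.73 ± 0.17, each higher in 14 of 14 spots. L-idonate dehydrogenase (VIT_16s0100g00290), an enzyme of tartaric acid synthesis, fell by 1.46 ± 0.25. Of 4 identifiers listed as 9-cis-epoxycarotenoid dioxygenases, enzymes of abscisic acid synthesis, 2 rose and 1 fell. After normexp background correction with quantile normalization 1 of the 2 rises did not pass (0.93). Among 45 stilbene synthase identifiers, 3 rose and 8 fell around a median of -0.07, whose sign depended on the scaling (0.06 after normexp background correction with quantile normalization and 0.16 after quantile normalization alone). The 3 with the largest falls did not pass after normexp with quantile normalization (-0.92, -0.98 and -0.65).

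In the competitive test of the lists (camera, 24 tests), the first interval gave adjusted p = 3.5e-08 for the phenylalanine ammonia-lyases (adjusted p = 0.13 with an estimated correlation), 1.7e-06 for the flavonoid core (adjusted p = 0.13 with an estimated correlation), 4.2e-05 for the anthocyanin branch (adjusted p = 0.21 with an estimated correlation) and 0.0046 for the NAC genes (adjusted p = 0.13 with an estimated correlation). The proanthocyanidin list (adjusted p = 0.077) and the stilbene synthases (adjusted p = 0.49) did not pass. Members past both thresholds numbered the same when p-values were adjusted over the list alone, here (12, 9, 13, 4, 1 and 11 in the order named) and for every list in the later intervals. Over all genes, 2310 rose and 3310 fell, and the change had one sign in at least 13 of 14 spots for 4477 of these 5620 genes (79.7%). Among genes without a listed name, VIT_19s0027g01810 was at least 1081-fold lower at time point 4, where no array had it well above background, and VIT_13s0019g01520 fell by 11.03 ± 0.93 log2 units. VIT_01s0011g05140 and VIT_01s0011g05110 rose by 8.56 ± 0.33 and 8.30 ± 0.40. With slide as a block 5582 genes passed and the list medians were -3.32, -2.28, -0.89 and 1.29 for the 4 lists that passed; within the 7 slides that held both time points they ranged from -4.67 to -2.41, -3.27 to -1.41, -1.94 to -0.54 and 0.67 to 1.99. After normexp and quantile normalization 1458 genes rose and 1917 fell.

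From time point 4 to time point 5 regulators and late-step genes of anthocyanin formation rose, while 9 of the 10 flavonoid core genes did not pass the test. The glutathione S-transferase GST4 (VIT_04s0079g00690), which takes part in moving anthocyanins to the vacuole, rose by 6.99 ± 0.47 log2 units (127-fold, adjusted p = 1.7e-20, higher in 14 of 14 spots). MYBA1 rose by 6.85 ± 0.44 (116-fold), MYBA2 by 6.46 ± 0.39 and the anthocyanidin glucosyltransferase UFGT (VIT_16s0039g02230) by 6.20 ± 0.34. At time point 4 these 4 genes were above background on 9, 5, 5 and 6 of the 14 arrays, so their fold changes start from levels near background. The acyltransferase 3AT (VIT_03s0017g00870) rose by 2.16 ± 0.21 and the O-methyltransferase AOMT (VIT_01s0010g03510) by 1.38 ± 0.23. In all, 6 of the 21 anthocyanin branch genes rose and 0 fell, with a median of 0.54. No flavonoid 3',5'-hydroxylase identifier passed both thresholds. Of the 10 flavonoid core genes only FLS passed, with a rise of 1.70 ± 0.26.

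Other groups moved in both directions over the same interval. NAC13 (VIT_02s0012g01040) rose by 3.17 ± 0.17 log2 units (9.0-fold), NAC33 (VIT_19s0027g00230) by 1.52 ± 0.23 and NAC11 (VIT_14s0108g01070) by 1.29 ± 0.28, while NAC26 and NAC60 changed by 0.20 ± 0.23 and 0.37 ± 0.17 and did not pass. The hexose transporter HT6 (VIT_18s0122g00850) rose by 1.51 ± 0.13 and WRKY19 (VIT_07s0005g01710) by 1.29 ± 0.09. Of the 4 identifiers listed as 9-cis-epoxycarotenoid dioxygenases, 3 rose, and 1 of these did not pass after normexp and quantile normalization (0.96). In the proanthocyanidin list 3 of 8 fell: the MYB regulators MYBPAR (VIT_11s0016g01300), by 2.33 ± 0.30, and MYBPA1 (VIT_15s0046g00170), by 1.17 ± 0.17, and leucoanthocyanidin reductase LAR2 (VIT_17s0000g04150), by 1.78 ± 0.22. After normexp and quantile normalization MYBPAR and MYBPA1 did not pass (-0.91 and -0.98). The regulator MYB5b (VIT_06s0004g00570) rose by 1.05 ± 0.09. Of the 13 phenylalanine ammonia-lyases 9 fell (median -1.13, or -0.78 after normexp and quantile normalization), and of the 45 stilbene synthase identifiers 19 fell and 0 rose (median -0.94, or -0.32 after normexp and quantile normalization).

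Adjusted p for this interval was 1.8e-06 for the anthocyanin branch (adjusted p = 0.16 with an estimated correlation), 0.0048 for the NAC genes (adjusted p = 0.13 with an estimated correlation), 0.0026 for the stilbene synthases (adjusted p = 0.56 with an estimated correlation) and 0.012 for the phenylalanine ammonia-lyases (adjusted p = 0.44 with an estimated correlation). The proanthocyanidin list (adjusted p = 0.36) did not pass, and the flavonoid core passed only with the spot number as a replicate block (adjusted p = 0.052 without it and 0.036 with it) and in array set 1 (0.017; adjusted p = 0.48 with an estimated correlation). Over all genes 1300 rose and 1904 fell, the smallest count of the 4 intervals and over the shortest of them. Of these 3204 genes, 2558 (79.8%) had one sign in at least 13 of 14 spots. Among genes without a listed name, VIT_08s0007g08330 and VIT_18s0089g00160 rose by 8.51 ± 0.59 and 7.58 ± 0.43 log2 units, and VIT_13s0019g02760 and VIT_08s0058g00210 changed by -7.52 ± 0.58 and -6.37 ± 0.58. With slide as a block 3119 genes passed, and the medians of the anthocyanin, NAC, stilbene synthase and phenylalanine ammonia-lyase lists were 0.52, 1.21, -0.87 and -1.09. Within the 9 slides that held both time points these medians ranged from -0.28 to 1.37, 0.08 to 2.62, -3.30 to 1.1 and -2.15 to 0.70, so that single slides went against the anthocyanin, stilbene synthase and phenylalanine ammonia-lyase directions; after normexp and quantile normalization 799 genes rose and 886 fell.

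Between time points 5 and 6 most measured genes along the path from phenylalanine to anthocyanins and to stilbenes rose. Of the 21 anthocyanin branch genes 18 rose and 0 fell, with a median of 2.65 log2 units. GST4 rose by a further 5.73 ± 0.47 (53-fold, adjusted p = 3.5e-17), UFGT by 4.03 ± 0.35, AOMT by 3.38 ± 0.24, MYBA2 by 3.23 ± 0.39 and the transporter anthoMATE3 (VIT_16s0050g00900) by 2.65 ± 0.15. Among the flavonoid 3',5'-hydroxylase identifiers the largest rise was 4.23 ± 0.24 in VIT_06s0009g03010. Of 10 flavonoid core genes 6 rose, with F3H1 at 3.46 ± 0.25 (11.0-fold), chalcone synthase CHS3 (VIT_05s0136g00260) at 3.36 ± 0.26 and CHS2 at 2.20 ± 0.20, and the median was 1.41. Of 13 phenylalanine ammonia-lyases 11 rose (median 2.64), led by VIT_13s0019g04460 at 3.70 ± 0.23. Of 45 stilbene synthase identifiers 38 rose (median 2.77, or 1.30 after normexp and quantile normalization), led by VIT_10s0042g00930 at 3.93 ± 0.49, and their regulator MYB15 (VIT_05s0049g01020) rose by 2.08 ± 0.16, whereas MYB14 (VIT_07s0005g03340) changed by 0.09 ± 0.20 and did not pass.

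L-idonate dehydrogenase and ANR fell over this interval. L-idonate dehydrogenase fell by 3.13 ± 0.24 log2 units (8.76-fold, adjusted p = 2.2e-18, lower in 14 of 14 spots) and ANR by 1.98 ± 0.29, the only 1 of the 8 proanthocyanidin genes that passed (list median -0.21). NAC11 rose by 2.69 ± 0.28, NAC33 by 1.68 ± 0.23 and NAC13 by 1.00 ± 0.17, and HT6 by 1.01 ± 0.13; the last 2 were just past the minimum change, and fell under it after quantile normalization with or without normexp (0.88 in both cases for NAC13, 0.95 and 0.97 for HT6). The hexose transporter HT2 (VIT_18s0001g05570) changed by -0.12 ± 0.14 and did not pass. None of the 4 listed 9-cis-epoxycarotenoid dioxygenases passed both thresholds.

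Adjusted p was 2.5e-13 for the anthocyanin branch (adjusted p = 0.11 with an estimated correlation), 1.1e-11 for the stilbene synthases (adjusted p = 0.21 with an estimated correlation), 3.9e-06 for the phenylalanine ammonia-lyases (adjusted p = 0.15 with an estimated correlation), 6.3e-05 for the flavonoid core (adjusted p = 0.15 with an estimated correlation) and 0.037 for the NAC genes (adjusted p = 0.21 with an estimated correlation), and 0.38 for the proanthocyanidin list. Over all genes 1957 rose and 3490 fell, and 4515 of the 5447 (82.9%) had one sign in at least 13 of 14 spots. Among genes without a listed name, VIT_00s0225g00230 and VIT_00s0394g00040 rose by 9.91 ± 0.57 and 7.72 ± 0.63 log2 units, and VIT_08s0007g06970 and VIT_18s0001g06690 changed by -6.76 ± 0.29 and -6.63 ± 0.30. With slide as a block 5549 genes passed and the medians of the 5 lists, in the order named, were 2.66, 2.72, 2.56, 1.39 and 1.02, with ranges within the 10 slides of 1.98 to 3.47, 0.33 to 3.78, 0.61 to 3.90, 0.90 to 2.09 and 0.86 to 1.96; the NAC list then no longer passed (adjusted p = 0.058), nor did it in array set 1 alone (0.054). After normexp and quantile normalization 1027 genes rose and 1700 fell.

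**Figure D2:**
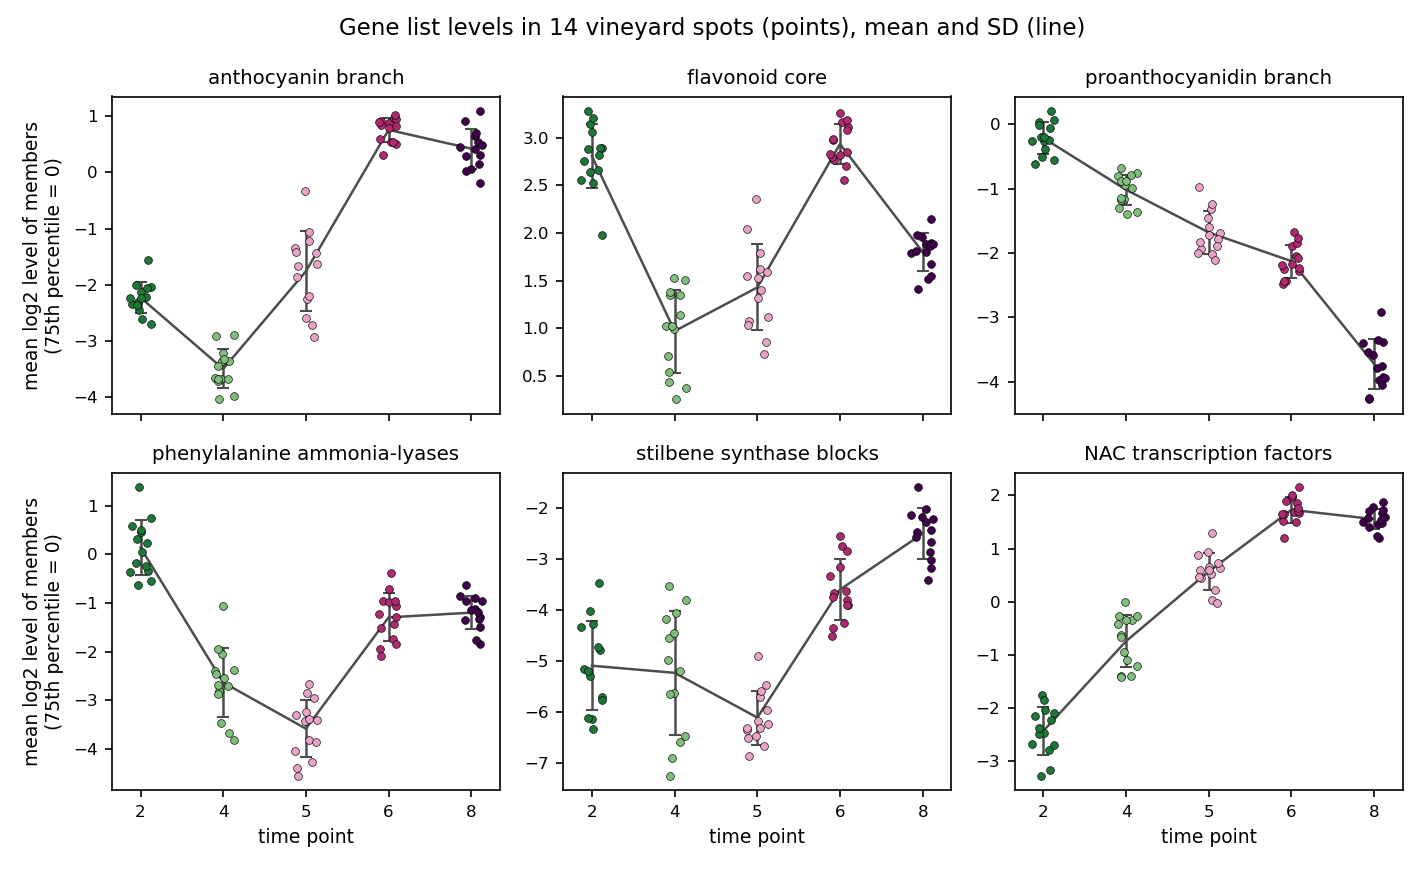
Mean log2 level of the measured members of 6 gene lists (y axes, relative to the 75th percentile of each array, which is 0) at the 5 time points (x axes); each point is 1 vineyard spot (14 per time point), and the line and bars are the mean and SD over spots. The anthocyanin branch and flavonoid core fall to time point 4 and are high at time point 6, where 18 of 21 and 6 of 10 members had risen since time point 5, and the proanthocyanidin branch is lowest at time point 8.

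From time point 6 to harvest, a regulator of flavonol synthesis, regulators and an enzyme of condensed tannin synthesis and the hexose transporters HT2 and HT6 fell, and part of the stilbene synthases rose. LAR1 (VIT_01s0011g02960), a leucoanthocyanidin reductase, fell by 6.07 ± 0.20 log2 units (67.1-fold, adjusted p = 7.7e-39), and was above background on 9 of 14 arrays at harvest. MYBPA2 (VIT_11s0016g01310), MYB5a (VIT_08s0007g07230) and MYBPA1 changed by -2.11 ± 0.24, -2.09 ± 0.10 and -1.84 ± 0.17 (MYBPA2 by -0.71 after normexp and quantile normalization, which did not pass), so that 4 of 8 proanthocyanidin genes fell and 0 rose (median -1.21, or -0.56 after normexp and quantile normalization). MYBF1 (VIT_07s0005g01210), a regulator of flavonol synthesis, fell by 4.07 ± 0.18 (16.8-fold), LDOX by 1.35 ± 0.16 and CHS3 by 1.02 ± 0.26, which made 3 of 10 flavonoid core genes (median -0.83). After quantile normalization with or without normexp CHS3 did not pass (-0.86 and -0.90). Of the 21 anthocyanin branch genes only AOMT passed, and fell by 1.1 ± 0.24, around a list median of -0.68. HT2 fell by 3.72 ± 0.14 and HT6 by 2.62 ± 0.14, in each of the 12 spots compared. L-idonate dehydrogenase fell by a further 1.54 ± 0.24.

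Among 45 stilbene synthase identifiers 22 rose and 0 fell (median 1.01), led by VIT_16s0100g01100 at 3.22 ± 0.40, which had been above background on 1 of 14 arrays at time point 6 and did not pass after normexp and quantile normalization (0.91). Of 13 phenylalanine ammonia-lyases only VIT_06s0004g02620 passed, and it fell by 1.72 ± 0.28. NAC11 rose by 1.70 ± 0.28, while NAC33 and NAC26 fell by 1.66 ± 0.23 and 1.12 ± 0.23. Of the 4 listed 9-cis-epoxycarotenoid dioxygenases 1 rose and 2 fell, and the rise did not pass after normexp and quantile normalization (0.96). Adjusted p was 0.0026 for the flavonoid core (adjusted p = 0.22 with an estimated correlation), 0.0046 for the proanthocyanidin list (adjusted p = 0.13 with an estimated correlation) and 0.015 for the stilbene synthases (adjusted p = 0.62 with an estimated correlation; 0.054 with the preset one in array set 1 alone). The anthocyanin branch passed only with the replicate block (adjusted p = 0.052 without it and 0.035 with it; adjusted p = 0.56 with an estimated correlation), and the NAC genes (adjusted p = 0.64) and phenylalanine ammonia-lyases (adjusted p = 0.93) did not pass.

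Harvest against time point 6 gave the most genes of the 4 intervals, with 4072 higher and 3468 lower, and 6540 of the 7540 (86.7%) had one sign in at least 13 of 14 spots. It was also the longest interval (samplings on days 0, 21, 30, 42 and 78), so the ranking of counts is not one of rates of change. The median change of all tested genes was 0.147 log2 units here and 0.032 after normexp and quantile normalization; relative to it the medians of the flavonoid core, proanthocyanidin and stilbene synthase lists were -0.98, -1.36 and 0.87. Among genes without a listed name, VIT_00s0270g00010 and VIT_04s0008g01530 rose by 8.19 ± 0.32 and 7.14 ± 0.54 log2 units, and VIT_17s0000g00820 and VIT_08s0007g01300 changed by -9.15 ± 0.41 and -7.82 ± 0.21. With slide as a block 7567 genes passed and the medians of these 3 lists were -0.77, -1.22 and 1.01, with ranges within the 9 slides that held both time points of -1.43 to -0.69, -1.69 to -0.18 and 0.30 to 2.45. After normexp and quantile normalization 1763 genes rose and 2202 fell.

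The design also asks which genes kept a difference between spots through the season. Within array set and after time point, 10 of 27207 genes differed between spots (moderated F test, limma, Benjamini-Hochberg), and 1627 (6.0%) had an unadjusted p under 0.05. The lowest adjusted p was 0.000157 for VIT_00s0388g00090, which stood 1.00 log2 units above the mean of its set in spot 12 and 1.08 below it in spot 3. VIT_00s0388g00020, of the same identifier block, had its extremes in the same spots (0.94 and -1.06, adjusted p = 0.017). VIT_05s0077g01080 was highest in spot 13 (0.45) and lowest in spot 5 (-0.39, adjusted p = 0.017), but did not pass after normexp and quantile normalization (adjusted p = 0.115). These 3 identifiers carry no listed name. No gene of the fixed lists was among the 10. NAC60 came closest, with an adjusted p of 0.081. In array set 1 alone 7 genes passed and in array set 2 alone 0 did (2038 and 673 with an unadjusted p under 0.05), so this result has no second set behind it. The count depended on single spots and samplings: without spot 1, 3, 12, 13 or 14 it was 2, 4, 5, 4 or 2, without time point 4, 5 or 6 it was 0 in each case (1420, 1094 and 1237 at an unadjusted p under 0.05), and with slide as a fixed term it was 36, of which 9 were among the 10. After normexp and quantile normalization it was 12, of which only 5 were among the 10.

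Scores of the gene lists (the mean log2 level of the members) gave no difference between spots that passed adjustment over 11 lists. The stilbene synthases had a permutation p of 0.015 and the anthocyanin branch 0.024 (adjusted p = 0.13 for both), and the stilbene synthases passed in array set 1 alone (adjusted p = 0.046) and without time point 6 (0.023). Labels permuted in this way shared slides more often than the real ones (median 27 pairs of arrays against 8). List scores were not tested with slide terms, so the lack of a call does not exclude a difference between spots. The SD of the anthocyanin branch score over the 14 spots was 0.28, 0.34, 0.71, 0.21 and 0.35 log2 units at time points 2, 4, 5, 6 and 8. At time point 5 this score ran from -2.93 in spot 14 to -0.33 in spot 11. The stilbene synthase score had SDs of 0.87, 1.21, 0.53, 0.60 and 0.50.

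How far apart the spots were at each stage was measured as the root mean square log2 difference of an array from the mean of the other arrays of its time point. This distance was 0.666 ± 0.158 at time point 2, 0.656 ± 0.120 at time point 4, 0.607 ± 0.091 at time point 5, 0.568 ± 0.131 at time point 6 and 0.589 ± 0.089 at time point 8 (SD, n = 14 spots). No pair of consecutive time points differed (exact two-sided sign-flip tests, 4 tests, adjusted p = 0.85, 0.70, 0.70 and 0.73; 0 with an unadjusted p under 0.05). This distance pools both array sets and holds differences between arrays and slides as well as between spots. At each time point the farthest array was of set 2 (spots 7, 2, 7, 4 and 2). Within the 9 spots of set 1 the mean distances were 0.61, 0.611, 0.596, 0.489 and 0.558, and no pair passed. Over the genes with a mean level above the median gene, 2 pairs did: the distance was lower at time point 6 than at time point 5 (0.287 against 0.356, in 11 of 14 spots, adjusted p = 0.018) and higher at time point 8 than at time point 6 (0.348, in 11 of 14 spots, adjusted p = 0.032). The farthest array was that of spot 7 at time point 2, at 1.089 against 0.875 for the next, and 88.3% of its probes were well above background against at most 76.0% on the other arrays of that time point.

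A transcriptome day was read for each array from its position along the line through the time point means of the other spots. The SD over the 14 spots was 2.00, 1.98, 1.93, 2.18 and 3.48 days at time points 2, 4, 5, 6 and 8, and no consecutive SDs differed (sign-flip test of absolute deviations, adjusted p = 0.94, 0.94, 0.94 and 0.36). At time point 5 the days ran from 26.7 in spot 13 to 32.6 in spot 5, and at harvest from 73.3 in spot 13 to 84.5 in spot 5. Over all 14 spots the days of these 2 samplings were hardly related (Pearson r = 0.06). The lowest and highest days lay in spots 6 and 8 at time point 2, 2 and 11 at time point 4, and 6 and 9 at time point 6. With the genes above the median level the spread at harvest exceeded that at time point 6 (SD 3.69 against 1.52 days, adjusted p = 0.043). A day is not an equal step of transcript change, because each segment of the line is read on the calendar. Principal component 1 ran from -61.4 to -10.5, 74.0 to 92.8 and 158.0 to 190.4 at time points 5, 6 and 8. The last interval was the longest. The nearest point can also be the bend at time point 6, while the end segment was extended at harvest. A larger SD in days at harvest therefore need not mean a larger difference in transcripts. Whether a spot that was ahead at one sampling was ahead at another was tested over the 10 pairs of time points, and none passed adjustment. The highest correlation was between time points 5 and 6 (Pearson r = 0.49, permutation p = 0.075, adjusted p = 0.68; Spearman rho = 0.63, p = 0.018, adjusted p = 0.18; n = 14), with r = 0.48 after the 2 spots farthest from the median were left out and 0.43 within the 9 spots of array set 1 (exact permutation p = 0.27). The 5 spots of set 2 were not tested alone. This pair passed after normexp and quantile normalization (r = 0.70, adjusted p = 0.027) and with the genes above the median level (r = 0.72, adjusted p = 0.017), and no pair that included harvest passed in any setting.

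**Figure D3:**
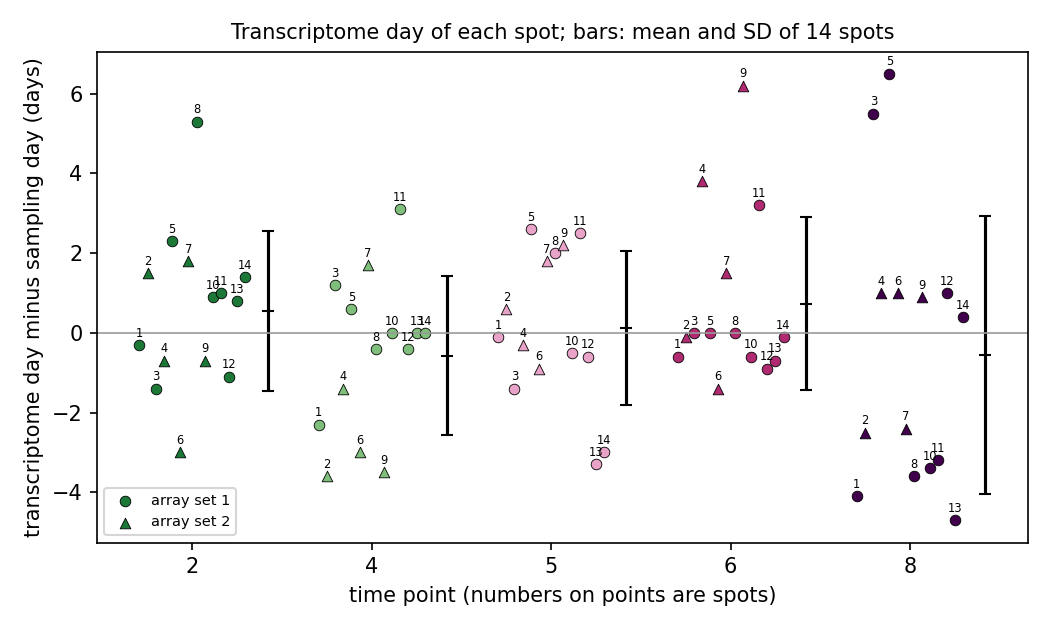
Transcriptome day minus sampling day (y axis, days) of each spot at the 5 time points (x axis); numbers are spots, circles are array set 1 and triangles array set 2, and the bars to the right of each group give the mean and SD of 14 spots. The SD is 2.00, 1.98, 1.93, 2.18 and 3.48 days from time point 2 to time point 8, and the order of spots differs between time points. Days are read on the sampling calendar and are not equal steps of transcript change.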

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

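The tests with slide as a fixed term or block, and those without the array of spot 7 at time point 2, were chosen only after the results were seen; the others were fixed before the data were examined. In the order of the 4 intervals, normexp with quantile normalization called 3375, 1685, 2727 and 3965 genes. Quantile normalization alone gave 6119, 3207, 5392 and 7110, which argues against that step as the cause. Normexp, its offset of 50 and the median intensity were not tested apart. No minimum change gave 15948, 13351, 16564 and 18491, which follows from the wider criterion. The other alternatives, including each spot left out, kept the counts of the main fit within 1.5 times (5560 to 5679, 3109 to 3332, 5281 to 5589 and 7275 to 7741 without 1 spot). The replicate block gave 5620, 3197, 5448 and 7538 genes and 18 list calls against 16, and apart from the 2 lists named in the report it changed no other call of a list or named gene. At harvest against time point 6 more genes rose than fell (4072 and 3468), but fewer did after normexp with quantile normalization (1763 and 2202), after quantile normalization alone (3418 and 3692) and with the stricter filter (3220 and 3231). The 10 genes that differed between spots became 77 without regard to array set, 0 in set 2 alone (5 spots; 673 genes with an unadjusted p under 0.05 in the limma F test), 16 with the stricter filter, 74 and 36 with slide as a random or fixed term, 21 without the array of spot 7 at time point 2, and 22, 0, 0, 0 and 22 without time points 2, 4, 5, 6 and 8 (the 3 counts of 0 with 1420, 1094 and 1237 at an unadjusted p under 0.05); leaving out 1 spot gave 2 to 15 (2, 4, 5, 4 and 2 without spots 1, 3, 12, 13 and 14). The cause was not tested, and the number of samples does not account for the time points, since leaving out any of them removed 14 arrays. After normexp with quantile normalization 12 genes passed, of which 5 were among the 10. Distances between spots gave 2 calls against 0, transcriptome day spread 1 and agreement of day 1 with the genes above the median level, and agreement of day also 1 after normexp with quantile normalization (adjusted p = 0.017 and 0.027, with the lowest of the 10 pairs from 0.017 to 0.85 over all settings); the cause was not tested. The correlation of day between time points 5 and 6 (r = 0.49, unadjusted p = 0.075) ran from 0.31 without spot 9 to 0.72 with the genes above the median level, and its unadjusted p was under 0.05 in 9 of 21 alternatives. List scores between spots gave 1 call in set 1 and 1 without time point 6 (adjusted p = 0.046 and 0.023, up to 0.57 in the others). With an estimated correlation in camera 0 of 24 list tests passed, 8 of them with an unadjusted p under 0.05. Of 320 values of named genes under alternatives, 297 kept direction and call, 23 fell under the minimum change, all after quantile normalization with or without normexp, and 0 reversed; of 168 list tests 146 kept their call, 19 lost it and 3 gained it. Among those named in the report, after normexp with quantile normalization MYBPAR and MYBPA1 changed by -0.91 and -0.98 from time point 4 to 5, and CHS3, MYBPA2 and VIT_16s0100g01100 by -0.86, -0.71 and 0.91 from time point 6 to 8, besides NAC13 and HT6. The 3 phenylalanine ammonia-lyases with the largest falls from time point 4 to 5 then changed by -0.78, -0.72 and -0.81, and the 3 such stilbene synthases by -0.80, -0.59 and -0.53. Averaging probes of a gene was void, since each identifier had 1 probe, and normexp used the median in place of the mean intensity. Signal over background limits folds that rest on dim probes, among them GST4, MYBA1, MYBA2 and UFGT before time point 5, LAR1 at harvest, VIT_06s0009g03140 (the change of -5.21, above background on 3 of 14 arrays at time point 4), and most of the genes without a listed name, which were above background on 0 to 10 of 14 arrays at 1 of their 2 time points. Fewer than 7 such arrays at a time point lay behind 4 of 11, 8 of 19, 14 of 38 and 3 of 22 stilbene synthase calls in the 4 intervals.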

Other observations

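The spread tests of single lists and of the members above background, the test of a wrong time point label, the comparison of arrays on different slides only, slide as a fixed term and the look at neighbouring identifiers were chosen only after the results were seen. At time point 5 the spots that were further along the transcriptome day had higher levels of the anthocyanin branch and of the 5 listed NAC genes. Over the 14 spots the anthocyanin branch score rose with the day read without the list members (Pearson r = 0.82, permutation p = 0.00034, adjusted p = 0.001 over 6 relations; Spearman rho = 0.84, p = 0.00034), with r = 0.87 after the 2 farthest spots were left out and 0.84 within the 9 spots of array set 1 (exact permutation p = 0.0053). The NAC score gave r = 0.86 (permutation p = 7e-05, adjusted p = 0.00042; rho = 0.81, p = 0.00071), 0.82 without the 2 farthest spots and 0.89 in set 1 (exact permutation p = 0.001). The flavonoid core gave r = 0.54 (adjusted p = 0.091), and the proanthocyanidin, stilbene synthase and phenylalanine ammonia-lyase lists gave r = -0.17, -0.29 and -0.17 (adjusted p = 0.57, 0.47 and 0.57). A hypothesis is that spots may differ at time point 5 in how far the colour genes have come on. The r of 0.82 describes this pattern but does not show it apart from the day itself, because genes that change along the season define the day and other genes of the same programme stay in it.

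The anthocyanin branch differed most between spots at time point 5, with an SD of 0.71 log2 units over 14 spots against 0.34 at time point 4 and 0.21 at time point 6. The test of each change in spread did not pass adjustment over 24 tests (time point 4 to 5, larger in 10 of 14 spots, p = 0.048, adjusted p = 0.35; time point 5 to 6, larger in 2 of 14 spots, p = 0.014, adjusted p = 0.17). Slides as its source are argued against: with slide terms removed the SD at time point 5 was 0.613, still over 1.5 times the next (0.343). Dim probes are argued against for the difference from the neighbouring time points: over the 12 members above background on all arrays of time points 4, 5 and 6 the SD was 0.516, against 0.144 at time point 4 (larger at time point 5 in 14 of 14 spots, unadjusted p = 0.00012, the smallest that sign flips can give) and 0.236 at time point 6 (larger there in 3 of 14 spots, unadjusted p = 0.016). They stay open for the difference from harvest, where the SD of these members was 0.37. A difference between spots in the timing of colour change could give this spread and is not shown by these tests. The stilbene synthase score moved the other way, from an SD of 1.21 at time point 4 to 0.53 at time point 5, with spots farther out in 2 of 14 cases (p = 0.0029, adjusted p = 0.070).

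Few genes kept a difference between spots. Slides left more in common than spots did: deviations of arrays on one slide correlated at 0.205, and those of one spot at -0.034. After removal of slide terms the correlation within a spot was 0.048, above that of permuted labels (one-sided permutation p = 0.0002, mean 0.0) but under the bound of 0.1 set beforehand. Slides thus hid no strong deviation shared by most genes. That permutation p does not separate spots from the layout of the slides. Labels permuted in this way put a median of 27 pairs of arrays of one label on a common slide, against 8 in the real layout. A correlation over all genes cannot show differences in few genes, so it does not exclude that slides hid such differences. The count rose from 10 to 36 with slide as a fixed term and was 74 with slide as a random one. Over pairs on different slides only, the value was 0.061 against 0.036 for permuted labels (p = 0.018). By best matches, that the numbers do not mark the same vines cannot be told apart from weak differences. An array matched its own number best at the next sampling in 12 of 56 cases against 8.0 by chance (permutation p = 0.096). The labels were permuted in the same way here, so the same limit holds. The value of 0.061 on different slides goes against numbers without meaning. Before slide terms were removed, the same pairs gave -0.053 against -0.056 for permuted labels (one-sided permutation p = 0.41), so the question stays open.

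The array of spot 7 at time point 2 stood farthest from its group, at 1.089. A wrong time point label is argued against by its transcriptome day of 1.8, within 5 days of its sampling. Weak signals are a candidate explanation: over the genes above the median level its distance was 0.375, rank 9 of 14, whereas over the lower-level genes it was 1.495 against 1.095 for the next. Its slide stays open, since the other array of time point 2 there lay at 0.662, rank 6 and close to the median of 0.632. Without this array 5705 genes passed between time points 2 and 4 and 21 differed between spots, and no biological explanation was tested.

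Chance in the assignment of labels was examined with 100 groupings each, the real one included. For the 4 intervals, time labels were exchanged within spots. Only the real one of the 100 groupings reached the real count in each interval (5620, 3204, 5447 and 7540, against highest other counts of 2620, 1686, 3598 and 4679). Exchanged labels mix the 2 time points, and most called genes changed with one sign in at least 13 of 14 spots. Fewer genes were therefore bound to pass, and this comparison does not by itself exclude chance. For the spots, 4 of 100 groupings reached the real 10 genes. This cannot decide on chance, because the permuted labels shared slides more often than the real ones did. The highest other count was 864, from a labelling that put 38 pairs of arrays of one label on a common slide, against 8 in the real layout and a median of 27, which points to the slides as a structure of the samples; with slide as a fixed term the real count was 36, of which 9 were among the 10. Of the 6 tested identifiers of the block that begins with VIT_00s0388, 2 differed between spots and 5 had an unadjusted p under 0.05; what these neighbouring genes encode is not given in the sources used here.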
